A study of Homo sapiens with 9 samples.

How the data were processed

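The series holds 9 RNA libraries from Raji, a human Burkitt lymphoma cell line, in 3 groups of 3 that the labels name by treatment: DMSO, hydroxyurea (HU) and thymidine-nocodazole (Thy-Noc). Libraries were made with a stranded poly(A)-type mRNA kit, per the labels' protocols. The submitters' processing notes name FastQC, Trim Galore, STAR and DESeq2 without versions, and the genome build GRCh38. The role of each tool, the counting tool, its annotation and its strand setting are not given in the sources used here.

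The authors deposited 1 table of expression values for all 9 libraries. Its name calls the values CPM, but the deposited values are whole numbers whose totals differ between libraries, from 74940755 to 110485145, so they were taken to be expected counts, that is, estimated counts rounded to whole numbers. No value is 0, and 274 of the 15436 genes stand at exactly 1 in all 9 libraries, which counts of single reads would not give. How the authors chose the listed genes is not given in the sources used here. For many genes the deposited expected count differs between replicates by very large factors, as a value for part of a gene would, so a value may not hold all reads of its gene.

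Gene identifiers were used as deposited. Of 15436, 15393 matched a table of gene names, and 15272 had coordinates in GENCODE release 29, which is on GRCh38, while 164 did not. The table's own names were not used, since 1890 of them read null and 37 had been altered by a spreadsheet. A further 45 genes with a shared symbol were kept under their identifiers. Numbers of annotated transcripts came from the same GENCODE release. Strand use in the counting is not stated, so overlapping and antisense genes, near-identical family members and genes with processed pseudogenes are uncertain.

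Expression was compared in R 4.3.3 with edgeR 4.0.16. Genes with a CPM of at least 1 in at least 3 libraries were kept, which left 11346, and libraries were scaled by TMM. A quasi-likelihood model with the 3 groups and no other term was fitted to all 9 libraries, leaving 6 residual degrees of freedom and a prior of 1.25. Each pair of groups was tested on 2 sides, with Benjamini-Hochberg adjustment over the 11346 genes and a threshold of 0.05. Standard errors of log2 fold changes were computed from the fold change and the F statistic. The test planned for CPM values was limma on log2(CPM + 0.5), with edgeR in its place if the values were counts. That replacement applied, and the limma result is given as an alternative. CPM values in the text use TMM-scaled library sizes. Shares of mitochondrial transcripts use the plain totals.

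Precision is set by the spread between libraries more than by depth: the median count of a tested gene was 1187. The chi-square per degree of freedom between libraries of the same group ran from 930 to 1230, so no library repeats the values of another in its group. Libraries of different groups were not compared in this way. Repeat sequencing of the same RNA is not excluded, since genes with very different values between replicates also raise this measure. A gene was called unsteady when, in at least 1 group, its highest library exceeded its lowest at least 10-fold after adding 0.5 CPM. Intervals on shares of genes are exact binomial intervals at 95% and cover counting error only.

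The comparisons, tests, alternatives, 30 gene lists and the rule for named genes were fixed before the data were examined. Named genes are the 10 highest and 10 lowest log2 fold changes of each comparison among called genes with a mean CPM of at least 5 and no overlap between groups, up to 4 called members per list and direction with a mean CPM of at least 2 (or, where none was called, the member with the largest change, as a value), a fixed set (among them MBD1, MYC, BCL6, RRM1, RRM2, CDKN1A, CCNB1, CCNE1, GAPDH and ACTB) and the 5 genes with the largest share of CPM. The text leaves out some of these. Lists cover the cell cycle, replication, DNA damage, innate and stress responses, B-cell states, methyl-CpG readers, mutators, growth, metabolism, apoptosis, fragile sites and other cell types. Lists with at least 5 tested members, 26 of the 30, were tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. This made 78 list tests.

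Alternatives were no filter, a CPM minimum of 5, median-of-ratios scaling, quantile normalization, no intensity trend, the replicate number as a block, only the 6 libraries of the groups compared, DESeq2 1.42.0, limma with a pseudocount of 0.1 or 1 CPM, and leaving out each library in turn. Chosen after the data were seen were limma with a pseudocount of 0.5 CPM, total-count scaling, robust dispersions, leaving out unsteady genes and testing only genes with at most 3 annotated transcripts. A fit without 1 library leaves 5 residual degrees of freedom.

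The steps were tested on simulated counts for the 11346 genes with 200 genes changed between HU and DMSO. A first simulation drew counts with edgeR's gene-wise negative binomial dispersions. There the edgeR test recovered 0% of changes of 2-fold or 4-fold and called 0 genes, and DESeq2 recovered 7% and 60% with 84 unchanged genes called. The simulation was then drawn again with the dispersions implied by the quasi-likelihood fit, which favours edgeR over DESeq2. There edgeR recovered 20% of 2-fold and 51% of 4-fold changes for HU against DMSO with 3 unchanged genes called, and called 0 genes for Thy-Noc against DMSO, where none were changed. On the same counts limma recovered 19% and 51%, with 3 unchanged genes called. DESeq2 recovered 49% and 75%, with 152 unchanged genes called for HU and 138 for Thy-Noc.

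To set the correlation of both treatments' changes beside chance, groups without change were simulated 20 times against the 3 DMSO libraries. Tables and plots were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.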

Results

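RNA was sequenced from Raji, an established human B-cell line derived from a Burkitt lymphoma. Cells had been given the solvent DMSO, hydroxyurea (HU) or thymidine with nocodazole (Thy-Noc), with 3 libraries per group. HU inhibits ribonucleotide reductase and so starves replication forks of deoxynucleotides, excess thymidine also stalls DNA synthesis, and nocodazole is a microtubule poison that holds cells in mitosis. Doses and times are not given in the sources used here. The summed counts were 77961480, 110485145 and 80590210 in DMSO, 75854730, 74940755 and 95298522 in HU, and 77332599, 76668973 and 105362232 in Thy-Noc. Of 15436 listed genes, 11346 were abundant enough to test. The labels do not say that the replicates came from separate cultures, so each p-value measures the spread between these samples, which may be technical.

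Many genes were unsteady between replicates. For 1839 of the 11346 tested genes (16.2%), libraries of the same group differed at least 10-fold. RRM1, the large subunit of ribonucleotide reductase, stood at 0.609, 538 and 0.623 CPM (counts scaled to library size) in the 3 DMSO libraries. It stood at 1.54, 0.829 and 1.95 CPM in HU and at 444, 471 and 523 CPM in Thy-Noc. ACTB, a cytoskeletal actin, stood at 23731, 223 and 16145 CPM in Thy-Noc. GAPDH, a glycolytic enzyme of nearly all cells, had only 16.5 ± 9.46 CPM in DMSO (mean ± SD, n = 3). The share of unsteady genes was 1.59% among 1009 genes with 1 annotated transcript, 6.0% among 1449 with 2 to 3, 14.9% among 5115 with 4 to 10 and 26.1% among 3732 with over 10.

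**Figure D1:**
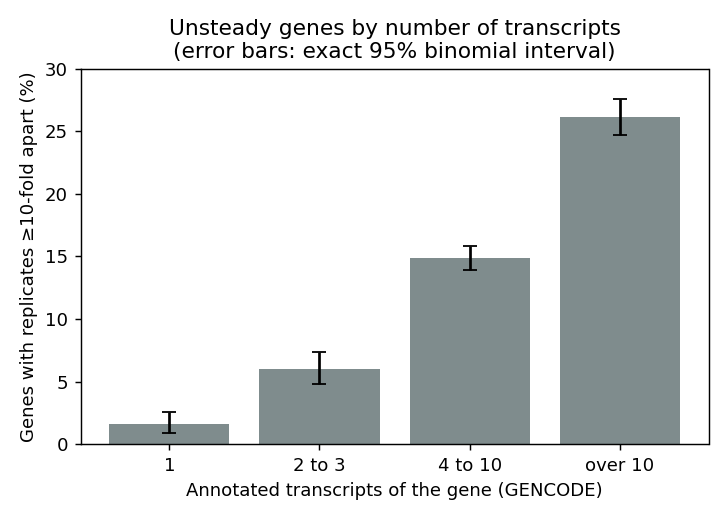
Percent of tested genes whose replicates within a group differed at least 10-fold (vertical axis), by number of transcripts annotated for the gene (horizontal axis), with exact 95% binomial intervals as bars. The percent runs from 1.59% at 1 transcript to 26.1% at over 10.

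The first comparison, HU against DMSO, asked how expression in these lymphoma cells responded to replication stress. Genes of mitosis were lower in HU. CDC20, an activator of the anaphase-promoting complex, stood at 204 ± 12.1 CPM in DMSO and 58.8 ± 15.4 CPM in HU (mean ± SD, n = 3 each), a log2 fold change of −1.79 ± 0.24 (SE). CENPF, a kinetochore protein, CKS2, a small partner of cyclin-dependent kinases, and TOP2A, the topoisomerase that untangles sister chromatids, had log2 fold changes of −1.17 ± 0.15, −1.06 ± 0.13 and −1.03 ± 0.15. Adjusted p for these 4 genes ran from 0.0165 to 0.0224 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Among 41 tested G2/M genes, 5 were lower past the threshold and 9 were lower when adjusted over the list alone, with a median log2 fold change of −0.79. The list's adjusted p was 4.59e-08 by camera, and adjusted p = 0.0603 with an estimated correlation. CCNB1, cyclin B1, had low values of 4.59 ± 2.49 CPM in DMSO and 4.99 ± 4.41 CPM in HU. It did not pass the test (log2 fold change 0.12 ± 0.84, edgeR quasi-likelihood adjusted p 0.965). The gene has 7 annotated transcripts, and its values may not hold all of its reads.

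SLBP, which binds the stem-loop of histone mRNAs, rose from 76.8 ± 2.73 to 257 ± 28.9 CPM, and CCNE2, a cyclin E, rose from 10.2 ± 0.70 to 67.6 ± 33.1 CPM (mean ± SD, n = 3 each). Their log2 fold changes were 1.75 ± 0.12 and 2.73 ± 0.49 (SE), with adjusted p of 0.00329 and 0.0377 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. These were the only 2 of 40 tested E2F and G1/S genes, which act at the start of S phase, past the threshold in either direction, and also the only 2 adjusted over the list alone. The list itself did not pass (camera adjusted p 0.663), and CCNE1 did not either, at 0.39 ± 0.25 (adjusted p 0.439 by the same edgeR test). Replication-dependent histone genes rose as a list of 10 tested members (median log2 fold change 1.36, camera adjusted p 0.00331, but adjusted p = 0.291 with an estimated correlation). Of these, H2BC12, a histone H2B gene, passed singly at 1.81 ± 0.38 (edgeR quasi-likelihood adjusted p 0.0492), and 4 passed adjusted over the list alone. Histone mRNAs of this class mostly lack a poly(A) tail, and the libraries were made with an mRNA kit.

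Nucleotide synthesis and DNA repair genes were lower as lists. None of 32 tested nucleotide synthesis genes passed by edgeR over all genes or adjusted over the list alone, 9 had an unadjusted p under 0.05, and DESeq2 called 6 and limma 0. Their median log2 fold change was −0.35, with a camera adjusted p of 0.00126 and adjusted p = 0.0603 with an estimated correlation. RRM1 had a log2 fold change of −6.96 ± 2.59 and RRM2 of 0.36 ± 0.94, with edgeR quasi-likelihood adjusted p of 0.184 and 0.899. Among 53 tested DNA repair and checkpoint genes, the median was −0.25 (camera adjusted p 0.0367, adjusted p = 0.143 with an estimated correlation). That call ended without DMSO replicate 3 (0.0627), without HU replicate 2 (0.154) and under quantile normalization (0.0616). POLK, a translesion polymerase, rose by 0.97 ± 0.17 on the log2 scale and MDC1, a scaffold at DNA breaks, fell by 0.82 ± 0.17, and these 2 were also the calls adjusted over the list alone. Of 25 tested p53 target genes, SESN2, a stress-induced sestrin, rose by 0.78 ± 0.16 and RRM2B, the p53-inducible subunit of ribonucleotide reductase, fell by 0.66 ± 0.13. Adjusted p for POLK, MDC1, SESN2 and RRM2B ran from 0.0327 to 0.0496 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Adjusted over the list alone, 7 p53 targets were higher and 2 lower. The list did not pass by camera (adjusted p 0.14, and adjusted p = 0.248 with an estimated correlation), while fry called it higher (adjusted p 0.0123). CDKN1A, the p21 inhibitor of cyclin-dependent kinases, stood at 13.1 ± 6.72 CPM in DMSO and 28.7 ± 25.1 CPM in HU, with an edgeR quasi-likelihood adjusted p of 0.388.

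Interferon-stimulated genes were higher in HU. IRF7, a transcription factor that drives interferon production, rose from 9.20 ± 5.94 to 123 ± 58.7 CPM, and IFI6 rose from 2.38 ± 0.87 to 72.7 ± 52.2 CPM (mean ± SD, n = 3 each). Their log2 fold changes were 3.74 ± 0.70 and 4.93 ± 0.85 (SE), beside 3.35 ± 0.46 for SAMD9L, an antiviral factor, and 2.32 ± 0.46 for IFIT5, a binder of viral RNA. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p of these 4 ran from 0.0222 to 0.0455. In all 4 the rise was weakest in HU replicate 2, as for IFI6 at 108, 12.7 and 97.7 CPM in HU replicates 1, 2 and 3. Of 31 tested members, 28 had a positive fold change, 6 were higher past the threshold and 20 were higher adjusted over the list alone. The camera adjusted p was 7.90e-10, with adjusted p = 0.213 with an estimated correlation.

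NF-kB targets and immediate early genes were higher as well. Among 24 tested NF-kB targets, 7 were higher past the threshold and 13 adjusted over the list alone. EBI3, a cytokine subunit, rose from 31.8 ± 9.17 to 137 ± 9.73 CPM (log2 fold change 2.11 ± 0.25). CCL22, a chemokine, TNF and TRAF1, an adaptor of TNF receptors, had log2 fold changes of 2.56 ± 0.53, 2.12 ± 0.32 and 1.85 ± 0.27. JUNB, a subunit of the AP-1 transcription factor, rose from 41.1 ± 1.76 to 109 ± 8.19 CPM (1.41 ± 0.10). DUSP5 and DUSP1, phosphatases that switch off MAP kinases, rose by 2.66 ± 0.46 and 1.41 ± 0.19, and ZFP36, which destabilises cytokine mRNAs, by 1.65 ± 0.32. Of 14 tested immediate early genes, 8 were higher past the threshold and 11 adjusted over the list alone. The adjusted p of these 8 named genes ran from 0.00329 to 0.0483 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. By camera, the NF-kB list had an adjusted p of 2.28e-07 and the immediate early list of 3.15e-09. Both calls held at adjusted p = 0.0164 and adjusted p = 0.0135 with an estimated correlation, the only 2 of the 13 lists called for HU against DMSO that did. MYC, placed among the immediate early genes, stood at 243 ± 193 CPM in DMSO and 52.7 ± 57.8 CPM in HU and did not pass (−2.21 ± 1.05, edgeR quasi-likelihood adjusted p 0.284).

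**Figure D2:**
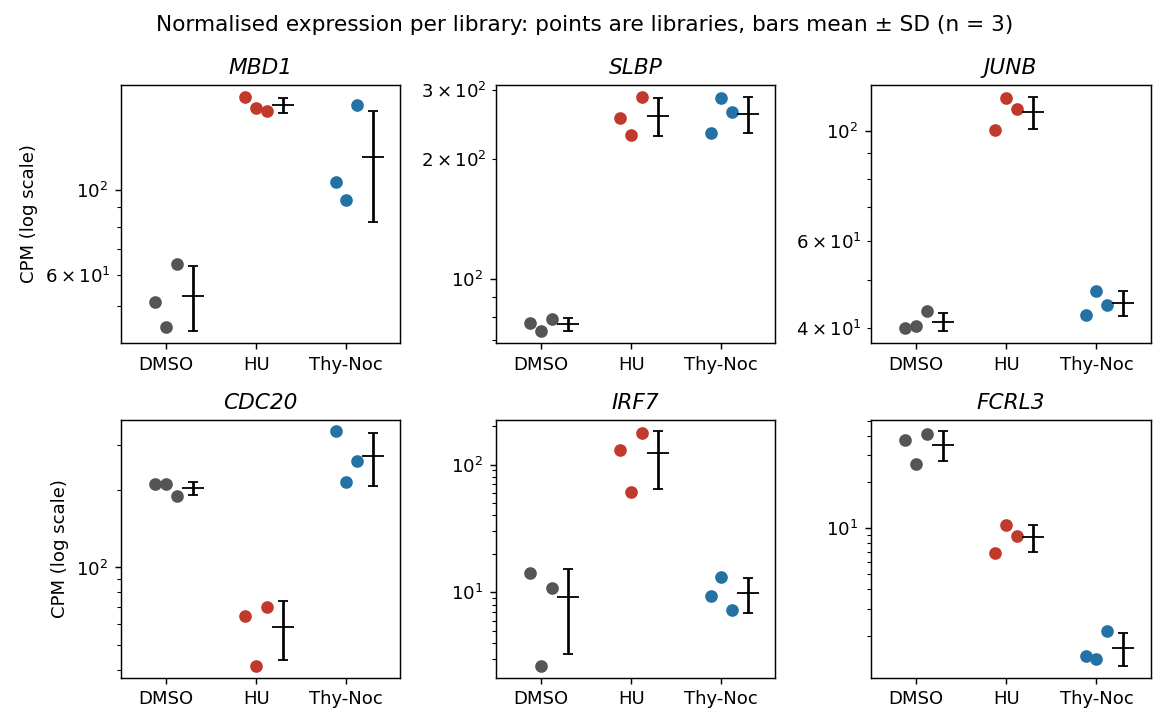
CPM (log axis) of MBD1, SLBP, JUNB, CDC20, IRF7 and FCRL3 in each of the 9 libraries, with points for libraries and bars for the group mean ± SD (n = 3 per group). MBD1 sits at 44.1 to 64.1 in DMSO, 160.1 to 174 in HU and 94.0 to 166 in Thy-Noc.

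MBD1, the methyl-CpG binding repressor named in the series title, was higher in HU. The gene (ENSG00000141644) lies on the minus strand of chromosome 18 from 50266882 to 50281774 in GRCh38 and has 27 annotated transcripts. It stood at 51.0, 44.1 and 64.1 CPM in DMSO and at 174, 163 and 160.1 CPM in HU, a 3.12-fold difference (log2 fold change 1.64 ± 0.24, adjusted p 0.0228 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The call ended without DMSO replicate 1, 2 or 3 (edgeR adjusted p 0.0894, 0.0856 and 0.0643) and without HU replicate 1 or 3 (0.0730 and 0.0729), while the log2 fold change stayed between 1.53 and 1.81. With the replicate number as a block the call also ended (log2 fold change 1.67, edgeR adjusted p 0.0604). MBD1 was the only 1 of 31 tested DNA methylation and methyl-CpG reader genes past the threshold, also adjusted over the list alone, and the list did not pass (camera adjusted p 0.341).

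Germinal centre genes moved in both directions, while the calls of the B-cell identity and plasma cell lists were lower. In the germinal centre list of 28 tested genes, CXCR5, the receptor that guides B cells into follicles, LMO2 and SPIB, both transcriptional regulators, rose by 2.52 ± 0.44, 2.49 ± 0.34 and 1.5 ± 0.17 on the log2 scale. BACH2, a repressor of plasma cell differentiation, fell by 1.40 ± 0.25 and GNA13, a G-protein subunit that confines germinal centre B cells, fell by 0.50 ± 0.07. FCRL3, an Fc receptor-like protein of B cells, fell from 35 ± 7.72 to 8.74 ± 1.79 CPM (−2.00 ± 0.28) and was the only 1 of 27 tested B-cell identity and receptor genes past the threshold, also adjusted over the list alone. MZB1, a chaperone of antibody assembly, and TXNDC5, a disulfide isomerase, fell by 0.75 ± 0.14 and 0.46 ± 0.08 and were the calls among 17 tested plasma cell genes. All 8 of these genes had an adjusted p between 0.0154 and 0.0412 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Adjusted over the list alone, 4 germinal centre genes were higher and 3 lower, and 3 plasma cell genes were lower. None of these lists passed, with camera adjusted p of 0.77 (germinal centre), 0.357 (plasma cell) and 0.742 (B-cell identity). The germinal centre list had a median of −0.16, a mean of 0.14 and a test in the lower direction, and the plasma cell list a median of −0.05, a mean of 0.17 and a test in the lower direction. BCL6, the germinal centre master regulator, had a log2 fold change of −0.46 ± 0.70, with an edgeR quasi-likelihood adjusted p of 0.799. Among 25 tested mutator genes and cofactors, TOP1, topoisomerase I, fell by 0.91 ± 0.14 and SUPT16H, a histone chaperone, by 0.56 ± 0.09, with edgeR quasi-likelihood adjusted p of 0.0263 and 0.0259, and 3 were lower adjusted over the list alone. That list had a camera adjusted p of 0.0277, with adjusted p = 0.248 with an estimated correlation, and the call ended without DMSO replicate 2 (0.0675) and without HU replicate 2 (0.0559), with a CPM minimum of 5 (0.1), under quantile normalization (0.0773) and without the unsteady genes (0.0548).

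HLA-DQA1 and HLA-DRB1, chains of MHC class II, rose by 1.59 ± 0.32 and 0.59 ± 0.09 on the log2 scale. They belong to a polymorphic family with near-identical copies, so their values are uncertain. Of 15 tested MHC class II genes, 2 were higher past the threshold, while 5 were higher and 1 lower adjusted over the list alone. The list's camera adjusted p was 0.0496, with adjusted p = 0.329 with an estimated correlation. It ended without DMSO replicate 1 (0.224), HU replicate 1 (0.13), HU replicate 3 (0.0905) or Thy-Noc replicate 3 (0.0652), with median-of-ratios scaling (0.0529) and without the unsteady genes (0.0647). Apoptosis regulators were higher as a list of 27 (median 0.43, camera adjusted p 0.011, adjusted p = 0.143 with an estimated correlation), which ended without HU replicate 2 (0.0549). BCL2A1, an anti-apoptotic relative of BCL2, rose by 1.80 ± 0.37 and BMF, a pro-apoptotic one, by 1.28 ± 0.24, and 4 were higher adjusted over the list alone. All 4 named genes had an adjusted p between 0.0245 and 0.0469 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

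Some genes of ribosome biogenesis and protein folding were lower. HSPD1, the mitochondrial chaperonin, fell from 18899 ± 1084 to 11185 ± 934 CPM (mean ± SD, n = 3 each), a log2 fold change of −0.76 ± 0.13 (SE). GAR1, a protein of small nucleolar particles, LYAR and WDR43, both nucleolar, fell by 1.11 ± 0.18, 0.85 ± 0.15 and 0.68 ± 0.10. Adjusted p for these 4 ran from 0.0245 to 0.0352 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 36 tested ribosome biogenesis and MYC-bound genes, 5 were lower past the threshold, while 13 were lower and 1 higher adjusted over the list alone (camera adjusted p 1.88e-05, adjusted p = 0.218 with an estimated correlation). Of 19 tested heat shock genes, HSPD1 alone passed and 5 were lower adjusted over the list alone (median −0.34, camera adjusted p 0.00386, adjusted p = 0.291 with an estimated correlation). That call ended without HU replicate 2 (0.0553). TUBA1B, an alpha-tubulin, fell by 0.67 ± 0.11 (edgeR quasi-likelihood adjusted p 0.0313) and was the only 1 of 13 tested tubulin genes past the threshold, also adjusted over the list alone. The tubulin list did not pass (camera adjusted p 0.438), with a median of 0.03 and a mean of −0.48.

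PPP1R15A, which restores translation after stress by dephosphorylating eIF2 alpha, rose from 6.46 ± 0.305 to 58.5 ± 14.2 CPM (log2 fold change 3.18 ± 0.30), and SLC7A5, an amino acid transporter, fell by 0.63 ± 0.12. They were the calls among 29 tested ATF4 and unfolded protein response genes, also adjusted over the list alone, with edgeR quasi-likelihood adjusted p of 0.00884 and 0.0419. The list did not pass (camera adjusted p 0.558), with a median of −0.09 and a mean of 0.32. ACAT2, a thiolase of sterol synthesis, rose by 0.94 ± 0.12 (edgeR quasi-likelihood adjusted p 0.0177) and was the only 1 of 24 tested cholesterol synthesis genes past the threshold, also adjusted over the list alone (camera adjusted p 0.277).

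Several metabolic lists had no member past the threshold over all genes or adjusted over the list alone. The 13 mitochondrially encoded genes, led by MT-CO3 at 0.51 ± 0.20, had 12 positive fold changes and a camera adjusted p of 0.00171, with adjusted p = 0.488 with an estimated correlation. Genes of the mitochondrial genome took 1.0%, 1.08% and 1.02% of counts in the DMSO libraries, 1.82%, 1.54% and 1.45% in HU, and 1.54%, 1.03% and 1.28% in Thy-Noc. EdgeR called 0 of these 13 genes, 6 had an unadjusted p under 0.05, DESeq2 called 1 and limma 0. For 76 cytosolic ribosomal protein genes the edgeR count was 0, with 10 at an unadjusted p under 0.05, 6 by DESeq2 and 1 by limma (camera adjusted p 0.839 in the lower direction, median 0.03). For 51 nuclear genes of oxidative phosphorylation it was 0, with 8 at an unadjusted p under 0.05, 5 by DESeq2 and 0 by limma (camera adjusted p 0.36). For 24 glycolysis and hypoxia genes it was 0, with 6 at an unadjusted p under 0.05, 4 by DESeq2 and 0 by limma (camera adjusted p 0.152). For 11 common fragile site genes it was 0, with 4 at an unadjusted p under 0.05, 3 by DESeq2 and 0 by limma (camera adjusted p 0.673). In the last 3 of these lists the members with the largest fold changes were unsteady between replicates, namely NDUFB3 (−6.10 ± 3.02), LDHA (5.0 ± 1.39) and LSAMP (−4.10 ± 1.66), and edgeR quasi-likelihood adjusted p for these 3 was 0.101 or above.

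Markers of other cell types were mostly too scarce to test. Of the T and NK cell, erythroid, fibroblast and epithelial, and myeloid lists, 3, 2, 2 and 0 genes were tested. EdgeR called 0 of them over all genes, while adjusted over the list alone 1 T-cell marker was lower and 1 fibroblast marker was higher. At an unadjusted p under 0.05 there were 2 T and NK cell markers (DESeq2 2, limma 0), 0 erythroid genes (DESeq2 0, limma 0) and 1 fibroblast or epithelial marker (DESeq2 1, limma 0). LCK stood at 9.79 ± 8.53 CPM in DMSO and 0.22 ± 0.19 CPM in HU, and COL1A1 at 2.61 ± 1.29 and 10.3 ± 2.99 CPM, with edgeR quasi-likelihood adjusted p of 0.197 and 0.0859. LCK was the T and NK cell marker with the largest fold change, not the 1 called over the list alone. It was unsteady, at 16.1, 0.0933 and 13.2 CPM in the DMSO libraries.

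The largest folds were in genes with few counts in 1 of the groups. CRIP3 rose from 0.12 ± 0.08 to 24.4 ± 0.71 CPM, SETD2, the histone H3 lysine 36 methyltransferase, from 1.41 ± 0.325 to 139.9 ± 31.8 CPM, and ZEB1, a zinc-finger repressor, from 0.81 ± 0.63 to 104 ± 15.8 CPM (mean ± SD, n = 3 each). Their log2 fold changes were 7.64 ± 0.54, 6.63 ± 0.47 and 7.0 ± 1.03 (SE). For CRIP3 it was 8.35 without DMSO replicate 3 and 4.58 by limma with a pseudocount of 1 CPM. ABHD17B, a depalmitoylase, fell from 9.92 ± 0.54 to 0.32 ± 0.09 CPM (−4.95 ± 0.27), TROAP, a spindle protein, fell by 5.42 ± 0.76, and CEP68, a centrosomal protein whose Thy-Noc libraries differed at least 10-fold, fell by 7.63 ± 1.54. All 6 had an adjusted p between 0.00274 and 0.0466 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

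In all, 227 genes were higher and 177 lower in HU (404 of 11346, 3.56%) at an adjusted p under 0.05, and 156 of the higher and 58 of the lower ones differed at least 2-fold. Total-count scaling put 72.7% of the calls on the higher side in place of 56.2%, and moved the median log2 fold change of all genes to 0.12. The count was 39 without DMSO replicate 1, 43 without DMSO replicate 2, 20 without DMSO replicate 3, 39 without HU replicate 1, 61 without HU replicate 3, 222 without Thy-Noc replicate 2 and 198 without Thy-Noc replicate 3. All 404 genes kept their direction and an unadjusted p under 0.05 in each of these and the other 2 fits without 1 library. That was likely in advance, since each fit shares all but 1 library with the fit that chose these genes. Of the 404, 11 stayed past the threshold in all 9. Of the 71 called genes named for this comparison, between 6 (without DMSO replicate 3) and 52 (without Thy-Noc replicate 1) stayed past it. The HU and DMSO libraries did not overlap for 3484 genes (30.7%), against the 10% that chance gives for 3 against 3.

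**Figure D3:**
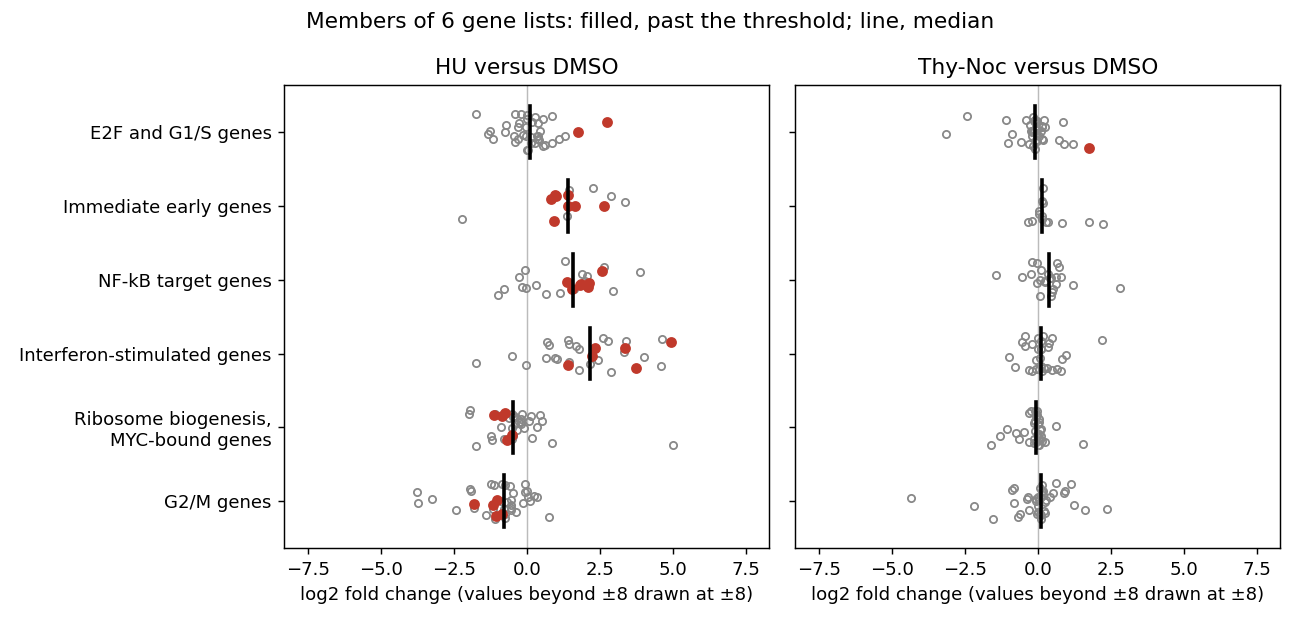
Log2 fold change (horizontal axis) of each tested member of 6 gene lists (vertical axis) for HU against DMSO and Thy-Noc against DMSO. Filled points are past the threshold, a line marks each median, and values beyond the plotted range are drawn at its edge. G2/M genes have a median of −0.79 under HU and 0.11 under Thy-Noc, and interferon-stimulated genes of 2.16 and 0.11.

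The second comparison, Thy-Noc against DMSO, asked what a block by thymidine and nocodazole changed in the same cells. Only 4 genes passed. SLBP rose from 76.8 ± 2.73 to 261 ± 27.0 CPM (mean ± SD, n = 3 each), a log2 fold change of 1.76 ± 0.12 (SE). CRIP3 rose from 0.12 ± 0.08 to 36.4 ± 5.17 CPM (8.22 ± 0.55) and SETD2 from 1.41 ± 0.325 to 70.0 ± 35.7 CPM (5.63 ± 0.45). FCRL3 fell from 35 ± 7.72 to 1.67 ± 0.40 CPM (−4.39 ± 0.31). Adjusted p for these genes ran from 0.00518 to 0.00995 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

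Mitotic genes did not pass under Thy-Noc. CDC20 stood at 271 ± 63.0 CPM against 204 ± 12.1 in DMSO, and CENPF at 148 ± 27.4 against 148 ± 8.41. EdgeR called 0 of 41 G2/M genes over all genes or adjusted over the list alone, 1 had an unadjusted p under 0.05, DESeq2 called 1 and limma 0, and the median was 0.11 with a mean of −0.03 (camera adjusted p 0.799). KIF23, a kinesin of cytokinesis, had the list's largest fold change, from 71.2 ± 5.36 to 3.48 ± 3.90 CPM. Interferon-stimulated genes had a median of 0.11 (camera adjusted p 0.641), NF-kB targets of 0.39 (0.0537) and immediate early genes of 0.16 (0.0929). EdgeR called 0 in each of these lists, over all genes or adjusted over the list alone, with 1, 2 and 0 members at an unadjusted p under 0.05 and 0 by DESeq2 or limma.

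MBD1 stood at 104, 94.0 and 166 CPM in Thy-Noc, with a log2 fold change of 1.19 ± 0.24 that did not pass over all genes (adjusted p 0.692 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0.00140 by DESeq2). It was the call of the methyl-CpG reader list adjusted over the list alone. VEGFA, an angiogenic growth factor, stood at 53.8 ± 14 CPM in DMSO and 3.87 ± 2.44 CPM in Thy-Noc (−3.80 ± 0.47, edgeR adjusted p 0.121), and FDXR, a mitochondrial reductase and p53 target, at 23.2 ± 4.41 and 99.98 ± 32.7 CPM (2.11 ± 0.35, edgeR adjusted p 0.356). Each was the call of its list, glycolysis and hypoxia or p53 targets, adjusted over the list alone. MYC, BCL6, RRM1, RRM2, CDKN1A, CCNB1, CCNE1, GAPDH and ACTB had log2 fold changes between −1.94 ± 0.97 (RRM2) and 1.42 ± 2.03 (RRM1), none of which passed.

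Ribosomal and mitochondrial transcripts were higher as lists, without a gene past the threshold over all genes or adjusted over the list alone. Of 76 cytosolic ribosomal protein genes, 59 had a positive fold change (median 0.13, camera adjusted p 0.00872, but adjusted p = 0.752 with an estimated correlation). By edgeR 0 of these genes passed, 7 had an unadjusted p under 0.05, and DESeq2 called 3 and limma 0. The list call ended without DMSO replicate 2 (0.0771), Thy-Noc replicate 1 (0.0657) or Thy-Noc replicate 3 (0.173). All 13 mitochondrially encoded genes had a positive fold change (median 0.34, camera adjusted p 4.80e-05, adjusted p = 0.752 with an estimated correlation), with 0 called by edgeR, DESeq2 or limma and 0 at an unadjusted p under 0.05. That call ended without Thy-Noc replicate 1 (0.0687), the library with a mitochondrial share of 1.54% beside 1.03% and 1.28% in the other Thy-Noc libraries. The remaining 24 lists with a set test had camera adjusted p of 0.0537 or above. Among them, median, mean and test differed in sign for G2/M, DNA repair, nucleotide synthesis, heat shock, B-cell identity, ATF4 and fragile site genes.

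In all, 3 genes were higher and 1 lower in Thy-Noc, with 510 at an unadjusted p under 0.05, and DESeq2 called 179. The total was 9 without DMSO replicate 1, 10 without DMSO replicate 2, 13 without DMSO replicate 3 and 11 without Thy-Noc replicate 1. SETD2 lost its call without DMSO replicate 2 (edgeR adjusted p 0.0552), and the other 3 genes kept theirs in all 9 fits without 1 library. The fold change of CRIP3 was 8.92 on the log2 scale without DMSO replicate 3 and 4.99 by limma with a pseudocount of 1 CPM. With only the 6 libraries compared, CRIP3 (edgeR adjusted p 0.0674) and SETD2 (0.0882) lost their calls, and with a replicate block edgeR called 0 genes (430 at an unadjusted p under 0.05). Groups did not overlap for 1131 genes (9.97%), against 10% by chance.

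The third comparison set HU directly against Thy-Noc, and so tested where the treatments differed from each other. CDC20 was lower in HU than in Thy-Noc, at 58.8 ± 15.4 against 271 ± 63.0 CPM (mean ± SD, n = 3 each), a log2 fold change of −2.21 ± 0.24 (SE). CKS2, CENPF and TOP2A were lower by the same contrast, at −1.30 ± 0.13, −1.17 ± 0.15 and −0.97 ± 0.15. Of 41 G2/M genes, 6 were lower past the threshold and 9 adjusted over the list alone (camera adjusted p 1.78e-08, adjusted p = 0.0545 with an estimated correlation). JUNB was higher in HU (1.28 ± 0.10), as were DUSP1 (1.14 ± 0.19), JUND (0.85 ± 0.13) and IER5 (0.80 ± 0.13), and 5 of 14 immediate early genes passed, 11 adjusted over the list alone (camera adjusted p 2.98e-08, adjusted p = 0.0196 with an estimated correlation). Adjusted p for these 8 named genes ran from 0.0119 to 0.0414 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

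TNF, the NF-kB inhibitor NFKBIE and EBI3 were higher in HU by 2.05 ± 0.32, 1.57 ± 0.22 and 1.45 ± 0.24 on the log2 scale, as 3 calls among 24 NF-kB targets, 9 adjusted over the list alone (camera adjusted p 1.26e-05, adjusted p = 0.0484 with an estimated correlation). SAMD9L and EPSTI1 were higher by 2.97 ± 0.45 and 1.72 ± 0.20, as 2 calls among 31 interferon-stimulated genes, 17 adjusted over the list alone (camera adjusted p 2.73e-10, adjusted p = 0.241 with an estimated correlation). VEGFA and FCRL3 were higher in HU than in Thy-Noc by 4.30 ± 0.49 (4.96 without Thy-Noc replicate 1) and 2.39 ± 0.28, and FDXR lower, at −2.87 ± 0.36. LMO2 and SPIB were higher (2.66 ± 0.34 and 1.15 ± 0.17) and BACH2 and GNA13 lower (−1.42 ± 0.25 and −0.45 ± 0.07), as were MZB1 (−1.03 ± 0.14) and TXNDC5 (−0.47 ± 0.08). PPP1R15A was higher by 2.91 ± 0.29. The adjusted p of these 15 genes ran from 0.0131 to 0.0443 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. MBD1 differed by 0.45 ± 0.24 and did not pass (edgeR quasi-likelihood adjusted p 0.363).

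Several growth lists were lower in HU than in Thy-Noc by camera at the preset correlation, and did not pass with an estimated correlation. HSPD1, LYAR and WDR43 had log2 fold changes of −0.80 ± 0.13, −0.90 ± 0.15 and −0.67 ± 0.10, and 4 of 36 ribosome biogenesis and MYC-bound genes passed, with 10 lower and 1 higher adjusted over the list alone (camera adjusted p 0.000314, adjusted p = 0.376 with an estimated correlation). HSPD1 was also the call among 19 heat shock genes, of which 5 were lower adjusted over the list alone (camera adjusted p 0.00875, adjusted p = 0.423 with an estimated correlation). That call ended without HU replicate 2 (0.116), without Thy-Noc replicate 1 (0.0692) and under quantile normalization (0.0797). EdgeR called 0 of 32 nucleotide synthesis genes over all genes or adjusted over the list alone, with 10 at an unadjusted p under 0.05, 6 by DESeq2 and 0 by limma (median −0.34, camera adjusted p 0.00143, adjusted p = 0.0545 with an estimated correlation). It also called 0 of 76 cytosolic ribosomal protein genes over all genes or adjusted over the list alone, with 13 at an unadjusted p under 0.05, 7 by DESeq2 and 0 by limma. Their list was lower at the edge of the threshold (camera adjusted p 0.0485, adjusted p = 0.578 with an estimated correlation), in the other direction under quantile normalization (0.988), and its median of −0.07 is nearer to 0 than the median of 0.16 that all genes had under total-count scaling. It also ended without DMSO replicate 1 (0.0505), 2 (0.0594) or 3 (0.0602), HU replicate 1 (0.0775) or 3 (0.338), or Thy-Noc replicate 1 (0.0692) or 3 (0.142), and with a CPM minimum of 5 (0.0540). The other 18 lists with a set test had camera adjusted p of 0.051 or above. Median, mean and test differed in sign for tubulin, plasma cell, B-cell identity and methyl-CpG reader genes.

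In all, 79 genes were higher and 120 lower in HU than in Thy-Noc (199 of 11346, 1.75%). Total-count scaling put 70.7% of its calls on the higher side in place of 39.7%. The count was 38, 51 and 40 without DMSO replicates 1, 2 and 3, 12, 110 and 31 without HU replicates 1, 2 and 3, and 48, 26 and 1 without Thy-Noc replicates 1, 2 and 3. All 199 kept their direction and an unadjusted p under 0.05 in these 9 fits, which was likely in advance since the fits share most libraries. Of the 199, 1, ABHD17B (−5.12 ± 0.27, edgeR quasi-likelihood adjusted p 0.00229), stayed past the threshold in all 9 fits. Of the 27 called genes named for this comparison, between 1 (without Thy-Noc replicate 3) and 14 (without HU replicate 2) stayed past it. Groups did not overlap for 2825 genes (24.9%), against 10% by chance.

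Because both treatments were compared with the same 3 DMSO libraries, their changes share chance values. Across the 11346 genes, which are not independent replicates, edgeR's log2 fold changes against DMSO had a Pearson correlation of 0.490 and a Spearman correlation of 0.397, and differences of mean log2 values of 0.477 and 0.401. On mean log2 values, 3 unchanged groups, DMSO included, were simulated together. They gave a mean Pearson correlation of 0.505 (0.473 to 0.541 in 20 draws) and a mean Spearman correlation of 0.437 (0.428 to 0.453). The observed Spearman correlation lay below the simulated range. The covariance was 0.524, 0.0761 above the simulated 0.448 (0.403 to 0.480). Without the unsteady genes, a comparison chosen after the results were seen, the Pearson correlation was 0.461, the Spearman correlation 0.388 and the covariance 0.212. The simulation gave 0.503 (0.482 to 0.536), 0.451 (0.435 to 0.473) and 0.126 (0.1199 to 0.138) for the same genes, so both correlations lay below and the covariance above the simulated range. The simulation gave every group the same spread per gene. In the real libraries the median SD of a gene (log2 scale) was 0.259 in DMSO, 0.322 in HU and 0.320 in Thy-Noc. A smaller spread in DMSO lowers both the correlation and the covariance that shared controls give. The correlations below the simulated range may come from this difference. The covariance lay above the range, the opposite of what a smaller DMSO spread gives, which argues against this difference as its source. Medians over genes do not give the spread of each gene, so no conclusion on a shared response is drawn. All 4 genes called for Thy-Noc were also called for HU in the same direction, 3 higher (CRIP3, SETD2 and SLBP) and 1 lower (FCRL3), where independent lists would share 0.0600 and 0.0156 genes. With 3 control libraries the controls cannot be split into sets of at least 2 libraries each, so part of any excess may come from the shared controls.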

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

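The alternatives chosen only after the results were seen were limma with a pseudocount of 0.5 CPM, total-count scaling, robust dispersions, leaving out unsteady genes and genes with at most 3 annotated transcripts. No called gene that the report names for a comparison changed direction under any alternative that tested it, while counts of calls moved widely. Counts are given as higher and lower for HU against DMSO (227 and 177), then Thy-Noc against DMSO (3 and 1), then HU against Thy-Noc (79 and 120), where they moved by over 1.5 times. With no filter they were 133 and 87, then 30 and 34 for HU against Thy-Noc. A CPM minimum of 5 gave 137 higher for HU against Thy-Noc, and no intensity trend gave 64 lower. With only the 6 libraries compared, which leaves fewer samples to estimate the spread, they were 25 and 13, then 2 lower, then 6 and 12. DESeq2 gave 1079 and 1056, then 102 and 77, then 900 and 926. On simulated counts it also called many unchanged genes. Quantile normalization gave 6 and 5 for Thy-Noc. The pseudocount of 0.1 gave 5 and 3 for Thy-Noc and 191 higher for HU against Thy-Noc, that of 1 gave 365 higher, 7 and 5, and 225 higher, and that of 0.5 gave 347 higher, 7 and 3, and 205 higher. Total-count scaling gave 102 lower and 46 lower in the comparisons with HU. Without unsteady genes, which leaves fewer and steadier genes, they were 412 and 305, then 238 and 233. Among the 2458 genes with at most 3 annotated transcripts they were 192 and 200 for HU against DMSO, within 1.5 times the main counts although those came from 11346 genes. For the same 2458 genes they were 0 and 0 for Thy-Noc by edgeR (95 at an unadjusted p under 0.05) and 172 and 176 for HU against Thy-Noc. Except where the wording above gives it, the cause was not tested.

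Without 1 library in turn, which leaves fewer samples, the ranges were 12 to 183 higher and 8 to 126 lower for HU against DMSO, 3 to 8 and 1 to 6 for Thy-Noc against DMSO, and 0 to 54 and 1 to 56 for HU against Thy-Noc. The lowest values came without DMSO replicate 3 for HU against DMSO and without Thy-Noc replicate 3 for HU against Thy-Noc. The correlation of both treatments' changes ran from 0.407 to 0.625, the highest without DMSO replicate 1.

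Of the 26 lists, camera called 13, 2 and 8 in the same order of comparisons. With an estimated correlation it called 2, 0 and 2, and the cause was not tested. Thy-Noc against DMSO had 4 with a CPM minimum of 5, 4 with the replicate block, 4 under quantile normalization and 0 by fry. For HU against DMSO, fry lost the camera calls of heat shock (fry adjusted p 0.0835), MHC class II (0.0721) and mitochondrially encoded genes (0.162). It kept the other camera calls there and added the p53 list (0.0123). Without 1 library the ranges were 9 to 14, 0 to 4 and 7 to 8. Cytosolic ribosomal protein genes in HU against Thy-Noc turned to the higher direction under quantile normalization (adjusted p 0.988, against 0.00202 to 0.338 without 1 library); the cause was not tested.

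The labels share replicate numbers across groups but do not say that a number marks a shared culture or day. Deviations of samples with the same number correlated at −0.035 to 0.040, and with different numbers at −0.054 to 0.033, and 4 of 9 libraries correlated best with their own number. Between HU and Thy-Noc the same number gave 0.040, 0.039 and 0.029, and different numbers −0.033 to −0.006. The same number gave −0.016, 0.0044 and −0.035 between DMSO and HU, and 0.032, −0.011 and 0.022 between DMSO and Thy-Noc. Correlations this small leave open whether the numbers pair the samples. With the replicate block, edgeR called 7 and 2 genes for HU against DMSO, 0 and 0 for Thy-Noc against DMSO (430 at an unadjusted p under 0.05) and 0 and 0 for HU against Thy-Noc (1956). The block takes degrees of freedom from the fit.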

Other observations

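The tests of unsteady genes by counting error and by transcript number, of the very large folds, of the spread and depth of the treatments and of other splits of the libraries were chosen only after the results were seen, as were the gene families that open this part. Several chromatin proteins of the high mobility group were lower in HU than in DMSO. Of 7 tested HMGB and HMGN genes, which bend DNA or bind nucleosomes, 5 were lower past the threshold and all 7 had a negative fold change. HMGB1, HMGB2, HMGB3, HMGN2 and HMGN5 had log2 fold changes of −1.06 ± 0.15, −0.74 ± 0.14, −0.59 ± 0.11, −1.26 ± 0.16 and −1.17 ± 0.14 (SE, n = 3 per group). These families were picked because members were among the calls, so a test for an excess of calls in them would say nothing, and none is given. Several of these genes have processed pseudogenes with which reads can be shared. Of 76 tested mitochondrial ribosomal protein genes, 59 had a negative fold change and 6 were lower past the threshold by the edgeR test, among them MRPS34 (−0.69), MRPS27 (−0.62) and MRPL16 (−0.55).

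Of 16 tested genes with TNFSF or TNFRSF symbols, ligands and receptors of the TNF family that do not include TNF itself, 4 were higher in HU past the threshold of the edgeR test. They were TNFSF9, a costimulatory ligand (1.62 ± 0.14), its receptor TNFRSF9 (2.77 ± 0.46), TNFSF4, the OX40 ligand (2.51 ± 0.45), and TNFSF10, the death ligand TRAIL (4.44 ± 0.74). TNFSF4 and TNFSF10 were near the floor in DMSO, at 0.737 to 1.02 and 0.364 to 0.750 CPM. For these and TNFRSF9 the rise was weakest in HU replicate 2, as for TNFSF10 at 14.9, 2.92 and 18.3 CPM in HU replicates 1, 2 and 3. Of the 16 genes, 13 had a positive and 3 a negative fold change. Of 14 MHC class I and antigen processing genes, 10 had a positive and 4 a negative fold change. Higher past the threshold were 4: HLA-B (1.15 ± 0.22), HLA-E (1.02 ± 0.12), the peptide transporter TAP1 (1.08 ± 0.14) and TAPBP (0.65 ± 0.09). HLA genes share reads with near-identical copies. MT-TH, MT-TL2 and MT-TS2, neighbouring mitochondrial tRNA genes, fell by 1.14, 1.1 and 1.08 in HU. These were the 3 calls among 18 tested mitochondrial tRNA genes, of which 5 of 11 on the plus strand, where these 3 lie, and 7 of 7 on the minus strand had a positive fold change. Poly(A) libraries hold tRNAs mostly as uncut precursors, so these values may not be levels of mature tRNA, and no test here bears on it.

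Replicates of the same group differed at least 10-fold for 1839 genes. Counting error is too small: with Poisson error alone around each group mean, 0 genes would differ so. A failed library would hold most of the odd values, but the library with the most held 12.6% of 2950 cases, close to an even share among 9. Values that cover only part of a gene, such as the reads assigned to 1 of its transcripts, remain a candidate explanation, since genes with over 3 annotated transcripts were unsteady more often than genes with at most 3 at equal mean CPM (Mantel-Haenszel odds ratio 5.43, 4.41 to 6.68). This could leave the fold change of a gene such as RRM1, GAPDH, CCNB1 or MBD1 (27 annotated transcripts) describing part of its reads. No biological explanation was tested.

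Among the 404 genes called for HU against DMSO, 15 had an absolute log2 fold change of at least 4, 9 higher and 6 lower. Whether values near the floor account for them stays open. By limma with a pseudocount of 1 CPM, 14 of the 15 stayed past the threshold and 9 kept an absolute log2 fold change of at least 4. A pseudocount shrinks any fold over a group near 0, real or not, so the loss of size does not decide it. A switch between parts of a gene may account for folds such as those of SETD2, ZEB1 and CRIP3: 13 of 278 calls with over 3 annotated transcripts and 2 of 125 with at most 3 had such folds (Fisher's exact test, two-sided p 0.163), which leaves it open. Real induction or loss in HU-treated cells also stays open and was not tested.

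HU gave 404 calls against DMSO and Thy-Noc 4. Whether noisier Thy-Noc libraries were the cause stays open. The median spread of a gene within Thy-Noc was 0.994 times that within HU, but Thy-Noc replicates 1 and 2 lay at −90.3 and 60.2 on the second principal component (13.7% of the variance), where HU ran from −26.4 to 30.03. Lower depth is argued against, since the mean total count of Thy-Noc was 1.05 times that of HU. A stronger response to HU at the dose and time used is a candidate explanation that was not tested, as neither is given in the sources used here. With 3 libraries against 3 there are 10 splits of the 6 libraries, too few for a share under 0.05. The real split gave 404 genes and the highest other 5 for HU against DMSO (1 of 10 splits as high). These counts were 4 and 5 for Thy-Noc against DMSO (4 of 10), and 199 and 8 for HU against Thy-Noc (1 of 10). Every other split mixes libraries of both groups, so any difference between the groups adds to its spread and lowers its count. The low counts of the other splits therefore do not show how many calls chance gives.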
